A study of Mus musculus with 4 samples.

How the data were processed

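Retinas of wild-type and Epac1-knockout mice were taken at postnatal day 17 after room air or after exposure to 70% oxygen from day 7 to day 12. Per the labels' protocols, the tissue was digested with papain for 20 min at 37 °C and passed through a 40 µm strainer, about 10000 cells per group were loaded, and libraries were made with the 10x Genomics 3′ kit, version 3.1. Each of the 4 groups was 1 library. The deposited matrices hold whole-number UMI counts per gene and barcode for 32285 features, per the file headers, and they are not normalized. Per the submitters' processing notes, bcl2fastq, Cell Ranger and STAR were used with the GRCm38 (mm10) build, and their versions are not given in the sources used here. The barcodes had been reduced to called cells before deposit, and the cell caller's settings are not given in the sources used here. Of the feature symbols, 78 occurred more than once, and 32235 features had a position in the GENCODE annotation of the same build.

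Cells with at least 300 genes and at most 20% mitochondrial UMIs were kept. Scrublet's automatic threshold marked 1, 2, 0 and 0 cells in WT RA, knockout-labelled RA, WT OIR and knockout-labelled OIR, which is too few for a working doublet call. The top-scoring cells were therefore removed at a rate of 0.8% of cells per 1000 barcodes, a rule fixed before the data were examined, which took out 643, 361, 644 and 861 cells. All 4 libraries were then clustered together without batch integration: 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0, which gave 33 clusters. Clusters were named from markers of 17 classes fixed before the data were examined, with at least 3 detected markers, and clusters whose leading genes went against their name stayed unnamed. A cluster led by Crhbp, Optc and Fbln1 was left unnamed by a threshold set after the data were seen, and counting it as Müller-like was tried as an alternative. Classes are called X-like because the names rest on these markers alone.

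UMI counts were summed per class and library and scaled to counts per 1000000 UMIs (CPM) with TMM factors computed from all 4 sums of a class. Ratios are given as log2 or as fold sizes with exact conditional binomial 95% intervals. Differences of responses have normal intervals from Poisson variances, summed counts exact Poisson intervals, and shares of cells exact Clopper-Pearson intervals. All of these cover counting error only, and none includes variation between animals. A sum of 0 was set at 3 counts, the limit that a count of 0 allows, and such folds are written as at least that size, with the larger sum taken as measured. Ratios were taken in the 6 classes with at least 50 cells in every library. With 1 library per group, no test was run and no p-value was computed. Sets of genes were picked by counting intervals, and their sizes are not counts of changed genes. The set of genes that differed by genotype label in both conditions, with bounds beyond 1.5-fold in all cells and in at least 3 classes, was fixed before the data were examined.

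Genes were named by a rule fixed before the data were examined. In Müller-like cells these were the genes with the largest interval bound nearest 0, 12 higher and 12 lower for WT OIR over WT RA and for knockout-labelled OIR over WT OIR, and 6 and 6 for the other comparisons. Eligible genes had at least 20 UMIs in the larger sum and a level at least 0.5 of that in the library's other cells. Mitochondrial, ribosomal protein and haemoglobin genes, Xist, Tsix, genes of the Y chromosome, and gene models named Gm plus digits or ending in Rik were left out. In other classes 3 higher and 3 lower genes were named. Gfap, Vim, Serpina3n, Vegfa, Glul, Rlbp1, Aqp4, Kcnj10, Rapgef3 and Rapgef4 were always named, and other genes are examples from the 2 highest and 2 lowest members of a list. Some genes that these rules name are not reported here.

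There were 22 gene lists, also fixed before the data were examined: reactive gliosis, Müller homeostasis, hypoxia and glycolysis, angiogenic factors, chemokines and NF-kB, interferon and MHC class I, complement, immediate early and dissociation, cholesterol synthesis, cAMP signalling, oxidative stress and metallothionein, unfolded protein response, Notch and progenitor, cell cycle, extracellular matrix, oxidative phosphorylation, phototransduction, photoreceptor stress, angiogenic endothelium, endothelial barrier, homeostatic microglia and activated microglia. Some genes stand in more than 1 list. Ctgf and Cyr61 were read under their current symbols Ccn2 and Ccn1, and Clec7a was not used here. For each list, the median log2 ratio of members with at least 20 UMIs over both sums was taken, with an interval from 400 Poisson resamplings. Its percentile was taken among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries.

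Response genes for the split comparison were chosen in a random 0.5 of the WT cells, with an interval bound beyond 1.5-fold, in classes with at least 400 cells per library. They were read in the remaining cells. Their number is the size of the chosen set and not a count of changed genes. Shares of cells with a UMI were computed after thinning each cell to 1000 UMIs, the largest multiple of 250 that kept at least 80% of Müller-like cells in every library. Müller-like cells were reclustered with 1000 variable genes at resolution 0.5. Free RNA was estimated from the library's pooled profile scaled to rod genes in the class.

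Over 21492 genes, the TMM factors computed for all 4 real Müller-like sums lay within 1e-06 of those of edgeR. The other statistics were tested on simulated counts with known changes. For WT OIR over WT RA, 95.9% of the intervals of 13153 genes held the true value, and 71.6% of genes with a simulated 1.5-fold change, 92.5% with a 2-fold and 100.0% with a 4-fold change had an interval on the true side of 0. For knockout-labelled OIR over WT OIR, the same genes gave 53.7%, 70.1% and 93.9%, and 96.2% of the intervals of 13565 genes held the true value. There the simulated knockout carried 0.5 of the WT log2 response. The true difference of each gene was therefore smaller than its simulated WT change of 1.5-fold, 2-fold or 4-fold. Of 200 random lists in the simulated WT comparison, 14.0% fell below percentile 5 or above 95. In the simulated split comparison, where the true median was 2.0, the median of 44 genes was read as 1.81 in WT, and as 0.89 in a knockout set at 0.5 of the WT response.

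Alternatives planned before the data were examined were at least 500 genes, at most 10% mitochondrial UMIs, no cell filter, no doublet removal, Scrublet's automatic threshold, resolutions 0.6 and 1.5, and Müller-like cells chosen per cell by markers. Others were CPM of the total, median-of-ratios scaling, equal weight per cell, thinning to 1 depth, subtraction of free RNA, and no minimum or at least 100 UMIs. Free RNA was not subtracted in rod-like and cone-like cells. For the split comparison, genes chosen in the knockout-labelled libraries, a 2-fold bound and exchanged parts were tried. The Optc cluster counted as Müller-like and Müller-like cells of at least 3000 UMIs were added after the data were seen. Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, python-igraph 0.11.9 and pandas 2.3.3 was used, and edgeR 4.0.16 in R 4.3.3 served only to check the TMM factors.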

Results

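Single-cell RNA sequencing was applied to retinas of mice at postnatal day 17 in 4 groups: wild type (WT) and Epac1 knockout, each raised in room air (RA) or subjected to oxygen-induced retinopathy (OIR). In OIR, newborn mice breathe 70% oxygen between postnatal days 7 and 12, which arrests and prunes the retinal capillaries, and the retina becomes hypoxic and grows abnormal vessels once the animals are back in room air. Epac1 is a cAMP-activated exchange factor for the small GTPase Rap. Going by the title and design text of the series, the comparison of main interest was the response of Müller glia, the radial glia that span the retina and serve its neurons, with and without Epac1. Each group was 1 library, and the number of animals pooled into it was not given in the sources used here. There was therefore no replicate check and no test: differences below are between libraries, and every interval is a 95% interval that covers counting error only.

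The WT RA library held 9176 barcodes and 26999393 unique molecular identifiers (UMIs, each standing for 1 captured RNA molecule), with a median of 1403 UMIs per barcode. The knockout-labelled RA library held 6843 barcodes and 28572661 UMIs with a median of 2731. The WT OIR library held 9273 barcodes and 27341922 UMIs with a median of 1479, and the knockout-labelled OIR library held 10675 barcodes and 32734051 UMIs with a median of 1437. After removal of poor barcodes and presumed doublets, 8111, 6240, 8040 and 9222 cells were used, in the same order of libraries, which is kept wherever 4 values are listed.

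Rapgef3, the gene that encodes Epac1 (ENSMUSG00000022469, minus strand of chromosome 15 from 97744770 to 97767972 in GRCm38), was detected in every library. Over all cells it had 78 UMIs in WT RA (exact Poisson interval 61.7 to 97.3), 112 in knockout-labelled RA (92.2 to 134.8), 146 in WT OIR (123.3 to 171.7) and 228 in knockout-labelled OIR (199.4 to 259.6), or 3.23, 4.32, 5.96 and 7.85 in counts per 1000000 UMIs (CPM). Endothelial-like cells held 31, 42, 83 and 109 of these UMIs and Müller-like cells 35, 39, 22 and 41, against 2, 0, 3 and 1 in the far more numerous rod-like cells. An unnamed cluster led by Optc held 1, 19, 24 and 49, from 9, 60, 63 and 87 cells. In Müller-like cells the ratio of the knockout-labelled to the WT library was 1.02 in room air (0.632 to 1.66) and 1.30 in OIR (0.758 to 2.296), so a loss of Rapgef3 RNA was not detectable. The OIR ratio, 0.38 on the log2 scale, was -0.48 when each cell was thinned to 1 depth, with 8 against 8 UMIs, and -0.36 with equal weight per cell. The labels do not state which part of the gene was deleted, and the 3′ tags counted here check nothing unless that part includes the end of the transcript. The genotype labels are therefore unchecked, and the libraries are called knockout-labelled throughout. Rapgef4, which encodes the related Epac2, had 752, 591, 827 and 903 UMIs over all cells and 2, 3, 8 and 9 in Müller-like cells.

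Rods made up most cells of every library. Amacrine-like, bipolar-like and pigment epithelium-like cells had smaller shares in the OIR libraries than in the room-air libraries of the same genotype label, and microglia-like and vascular cells had larger ones. Amacrine-like cells were 2.31% of cells in WT RA and 1.92% in knockout-labelled RA, but 0.572% in WT OIR (exact binomial interval 0.419 to 0.762) and 0.314% in knockout-labelled OIR (0.211 to 0.451). Microglia-like cells were 0.456%, 1.03%, 1.85% and 1.89% of cells, endothelial-like cells 1.44%, 2.20%, 2.75% and 3.30%, and mural-like cells, the pericytes and smooth muscle of the vessel wall, 0.740%, 0.817%, 1.31% and 1.30%. Bipolar-like cells were 10.1% and 14.4% in the RA libraries against 8.21% and 5.38% in the OIR libraries, and pigment epithelium-like cells 0.358% and 0.240% against 0.050% and 0.108%. The pigment epithelium-like shares rested on 29, 15, 4 and 10 cells. Their intervals overlapped between knockout-labelled RA (0.135 to 0.396) and knockout-labelled OIR (0.052 to 0.199). Müller-like cells were 10.6% in WT RA (9.98 to 11.3), 13.4% in knockout-labelled RA (12.6 to 14.3), 11.8% in WT OIR (11.1 to 12.5) and 14.3% in knockout-labelled OIR (13.6 to 15.03). Rod-like cells were 69.9%, 58.3%, 68.5% and 69.1%, and cone-like cells 2.10%, 4.15%, 2.23% and 2.17%. The knockout-labelled RA library, with the lowest rod and the highest cone and bipolar shares, was also the deepest per barcode, and papain digestion and the 40 µm strainer act on all shares. A cluster led by Optc was kept out of the named classes by a threshold set after the data were seen, and it held 0.111%, 0.962%, 0.784% and 0.943% of cells.

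**Figure D1:**
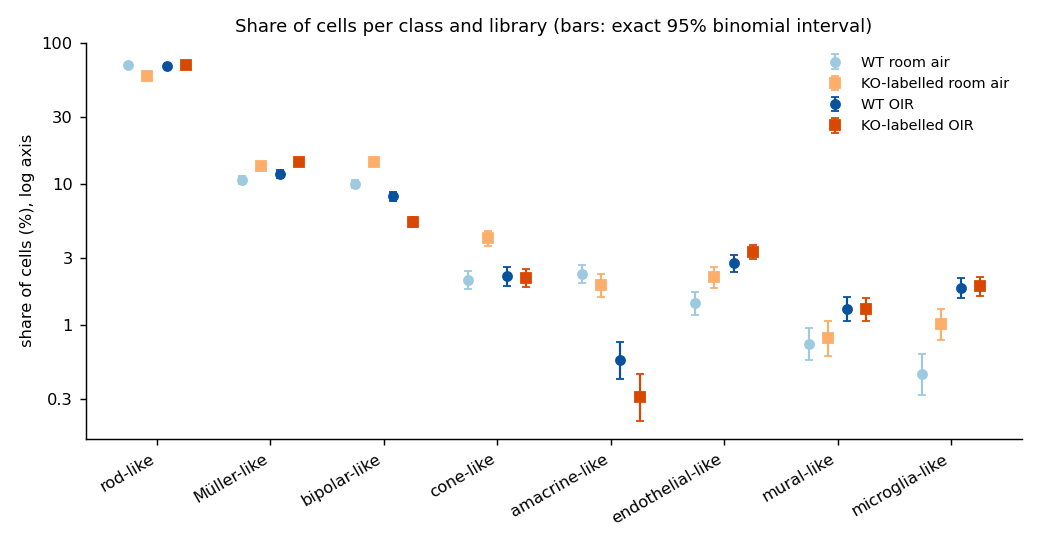
Share of all used cells (percent, log axis) that fell in each of 8 cell classes, 1 point per library with its exact 95% binomial interval. Amacrine-like cells lie at 0.572% and 0.314% in the OIR libraries against 2.31% and 1.92% in the room-air libraries, and microglia-like cells lie at 1.85% and 1.89% against 0.456% and 1.03%.

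The effect of OIR in wild-type Müller glia was taken from the summed UMIs of Müller-like cells in WT OIR over WT RA. Genes of reactive gliosis, the injury response of glia, were higher in WT OIR, genes of the resting functions of Müller glia were lower, and genes of hypoxia and of the unfolded protein response were higher. All 18 measured members of the gliosis list were higher, with a median log2 ratio of 3.30 (2.67 to 3.69), above all of 10000 random lists of matched expression. Lcn2, which encodes an iron-siderophore carrier of acute inflammation, was at least 450.2-fold higher and Timp1, a metalloproteinase inhibitor, at least 436-fold, both from 0 UMIs in WT RA. Gfap, the glial intermediate filament that marks reactive glia, was 67.5-fold higher (41.4 to 118) with 1132 against 16 UMIs, Serpina3n, a protease inhibitor of reactive astrocytes, 201-fold (68.4 to 977) and Vim, a constitutive filament of these cells, 2.88-fold (2.78 to 2.97). Stat3 and the copper oxidase gene Cp showed the smallest ratios of the list, 1.96-fold and 1.26-fold.

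The homeostasis list had 15 of 19 members lower in WT OIR and a median of -0.90 (-0.95 to -0.86), below all random lists. Glul, the glutamine synthetase that turns glutamate into glutamine, was 2.53-fold lower (2.48 to 2.57), the water channel gene Aqp4 2.20-fold (2.08 to 2.33), the potassium channel gene Kcnj10 2.15-fold (1.92 to 2.41), the retinaldehyde-binding protein gene Rlbp1 1.93-fold (1.88 to 1.98) and the carbonic anhydrase gene Car14 2.37-fold. The glial transcription factor gene Sox9 was an exception at 1.36-fold higher. The Notch and progenitor list, with 8 of 9 members lower, had a median of -0.54 (-0.84 to -0.36), and its members Hes1 and Id2 were 2.29-fold and 2.43-fold lower.

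Hypoxia and glycolysis genes had 20 of 22 measured members higher and a median of 1.40 (1.26 to 1.5; above all of the random lists). The vasoactive peptide gene Adm was 264-fold higher (72.8 to 2187) from 2 UMIs, and Egln3, an oxygen-sensing prolyl hydroxylase induced by hypoxia-inducible factor, 132-fold (44.9 to 644) from 3. Vegfa, the main angiogenic growth factor, stood at 827 CPM in WT OIR and 242 in WT RA, a 3.42-fold difference (3.20 to 3.66). The angiogenic factor list had a median of 1.01 (0.70 to 1.24) with 11 of 13 members higher, among them Angptl4 (12.7-fold, from 3 UMIs, 4.05 to 64.3) and Pgf (6.62-fold), while Ptn was 1.46-fold lower. In the unfolded protein response list 10 of 12 members were higher, with a median of 1.38 (1.23 to 1.47). They included the asparagine synthetase gene Asns (34.5-fold) and Trib3 (17.2-fold, from 2 UMIs, 4.42 to 147), both targets of Atf4, whereas Herpud1, a target of the endoplasmic reticulum branch, was 2.33-fold lower.

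Inflammatory genes differed less evenly. Interferon and MHC class I genes had a median of 0.73 (0.45 to 0.96) with 13 of 18 members higher, from Gbp2 (4.25-fold) and Isg15 (3.98-fold) to Ifit3, which was 1.90-fold lower. Of the chemokine and NF-kB list, 8 of 11 members were higher, with a median of 0.54 (0.10 to 0.80). Ccl2, the monocyte attractant, was 291-fold higher (51.8 to 11527) from 1 UMI and Cxcl1 61.0-fold (10.6 to 2448), also from 1 UMI, while the cytokine genes Il18 and Il33 were 1.88-fold and 1.57-fold lower. The complement list had 5 measured members and a median of 1.01 (0.06 to 1.84), with C4b 10.8-fold and Serping1 3.33-fold higher, and the median was -0.07 with no minimum of UMIs. Photoreceptor stress genes were higher in 7 of 7, with a median of 1.72 (1.64 to 1.78), for example the metallothionein gene Mt2 at 7.97-fold. Immediate early and dissociation genes had a median of 0.26 (0.20 to 0.31) with 14 of 17 higher, among them Atf3 (11.0-fold) and Ier3 (8.05-fold), and Dusp1 was 2.01-fold lower.

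The other lists had medians nearer 0 or few measured members. The median was 0.33 for extracellular matrix (0.21 to 1.16; 9 of 13 higher), where Tnc was 58.2-fold higher from 2 UMIs (15.8 to 486) and Bcan 6.82-fold lower. It was 0.26 for oxidative phosphorylation (0.20 to 0.31), 0.21 for oxidative stress and metallothionein (0.07 to 0.40), 0.17 for cholesterol synthesis (0.00 to 0.36), 0.07 for cell cycle (-0.16 to 0.55), 0.04 for cAMP signalling (-0.08 to 0.11) and -0.08 for phototransduction (-0.14 to 0.02). Within these, the cyclin gene Ccnd1 was 3.24-fold higher, the sterol synthesis gene Sqle 2.31-fold higher and Insig1 2.96-fold lower. Lists named for other cell types gave 1.45 for angiogenic endothelium (1.14 to 1.90), a list that also holds Adm and Pgf, 0.58 for activated microglia (0.49 to 0.88), -0.19 for homeostatic microglia (-0.67 to 0.10; 3 measured) and -0.83 for endothelial barrier (-1.13 to -0.32; 5 measured), where Slco1c1 was 7.50-fold lower. The endothelial barrier median was 0.00 with Müller-like cells chosen by per-cell markers and 0.30 after thinning.

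Among genes named by size of the ratio, those higher in WT OIR besides Lcn2, Timp1, Adm, Serpina3n, Ccl2, Egln3 and Gfap were Anxa2, an annexin (348-fold, 135 to 1278), Akap12, a scaffold of protein kinase A (178-fold, 93.5 to 389.8), Areg, a ligand of the epidermal growth factor receptor (at least 58.2-fold), Hmox1, the haem oxygenase (113-fold, 43.9 to 417), and Fosl1, an AP-1 subunit (at least 46.4-fold). The genes named as lower were Etnppl, an enzyme of ethanolamine phosphate breakdown (49.7-fold, 30.4 to 87.3), Fkbp5, a co-chaperone of the glucocorticoid receptor (27.6-fold, 19.4 to 40.6), Fam107a (48.0-fold), Col25a1 (44.0-fold), BC055402 (16.0-fold), the kinase gene Ptk2b (68.2-fold to 1 UMI, 11.8 to 2733), Arrdc2 (15.1-fold), the zinc finger gene Zbtb16 (12.2-fold), Shisal2b (9.74-fold), Prr5 (10.8-fold), Crispld1 (9.92-fold) and Mpp3 (9.85-fold). WT RA stood apart from knockout-labelled RA for several of these, with Fkbp5 at 179.5 against 9.40 CPM, Arrdc2 at 79.97 against 8.42, Zbtb16 at 114 against 18.4 and Ptk2b at 13.9 against 0.979. Free RNA, traced by rod genes, came to 14.7% and 17.3% of Müller-like UMIs in WT RA and WT OIR. In WT OIR, Müller-like UMIs came mainly from clusters 7 and 22 (42.8% and 38.5%), and in WT RA from cluster 7 (87.6%). The gliosis median was 1.90 when only members with at least 100 UMIs over both sums were kept.

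The effect of the genotype label under OIR was taken from knockout-labelled OIR over WT OIR. This ratio shares the WT OIR library with WT OIR over WT RA. In every class, a deviation of that library alone would therefore move both ratios in opposite directions. In the knockout-labelled library, gliosis, hypoxia and unfolded protein response genes were lower than in the WT library and Müller homeostasis genes were higher. The gliosis list had 17 of 18 measured members lower and a median of -1.03 (-1.22 to -0.89), below all random lists, that is, a level 2.05-fold lower. Lcn2 was 11.6-fold lower (9.89 to 13.6), Timp1 6.52-fold (5.75 to 7.41), Serpina3n 5.65-fold (4.74 to 6.76), Gfap 2.87-fold (2.59 to 3.18) and Vim 1.29-fold (1.26 to 1.31). Socs3, the feedback inhibitor of Stat3 signalling, was the exception at 1.80-fold higher (1.57 to 2.08), and C4b had a log2 ratio of -0.00 (-0.33 to 0.32). The gliosis median was -0.60 after each cell was thinned to 1 depth and lay between -1.18 and -0.90 under the other alternatives run.

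Homeostasis genes had 16 of 19 members higher in the knockout-labelled OIR library and a median of 0.57 (0.51 to 0.60; above all random lists). Glul was 1.66-fold higher (1.63 to 1.69), Kcnj10 1.62-fold, Rlbp1 1.56-fold, Aqp4 1.55-fold, Car14 1.71-fold and the receptor gene Gpr37 1.75-fold, while the cystine transporter gene Slc7a11 was 2.48-fold lower (1.92 to 3.21) and Sox9 1.23-fold lower. The Notch and progenitor list was higher in 10 of 11 members with a median of 0.58 (0.38 to 0.85), led by Hes5 (2.05-fold) and Id2 (1.86-fold). Hypoxia and glycolysis genes were lower in 21 of 23 with a median of -0.54 (-0.57 to -0.45), Egln3 by 5.09-fold (4.13 to 6.30) and Car9 by 8.11-fold with 3 against 17 UMIs (2.35 to 43.2). Vegfa was 1.25-fold lower (1.198 to 1.30) at 661 CPM. Unfolded protein response genes were lower in 10 of 12 with a median of -0.73 (-0.80 to -0.61), Asns by 5.08-fold and Chac1 by 4.93-fold (2.29 to 11.8). Photoreceptor stress genes were lower in 6 of 7 with a median of -1.10 (-1.37 to -0.94), and the metallothionein genes Mt2 and Mt1 were 6.25-fold and 4.201-fold lower.

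Not all groups followed. Interferon and MHC class I genes had 10 of 19 members higher and a median of 0.05 (-0.17 to 0.14), and H2-D1 was 1.37-fold lower. Angiogenic factors had a median of -0.12 (-0.25 to 0.21), with Angptl4 8.17-fold lower and Ptn 1.42-fold and Ccn1 1.32-fold higher. Immediate early genes had 13 of 17 higher and a median of 0.34 (0.15 to 0.42), with Dusp1 2.21-fold higher and Ier3 1.98-fold lower. Complement genes had a median of 0.61 (0.10 to 1.10) over 6 members, with Cd59a 2.66-fold higher, but -0.05 with free RNA subtracted and -0.00 with at least 100 UMIs. Phototransduction genes, which Müller glia do not express, had a median of 0.26 (0.17 to 0.32), beside a free RNA share of 18.3% in this library and 17.3% in WT OIR. Chemokine and NF-kB genes had a median of -0.37 (-0.81 to 0.01), extracellular matrix genes -0.31 (-0.72 to 0.00), angiogenic endothelium genes -0.30 (-0.67 to -0.03) and activated microglia genes -0.21 (-0.40 to -0.13). The median was -0.18 for cholesterol synthesis (-0.37 to -0.02), -0.17 for homeostatic microglia (-0.40 to 0.59), 0.29 for endothelial barrier (-0.18 to 0.64), 0.01 for cell cycle (-0.18 to 0.33), -0.01 for oxidative stress and metallothionein (-0.24 to 0.09) and -0.00 for cAMP signalling (-0.09 to 0.07). Oxidative phosphorylation had a median of -0.07 (-0.10 to -0.02), which was 0.10 with each cell weighted equally and 0.12 after thinning.

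Genes named by size as lower in the knockout-labelled OIR library, besides Lcn2, were the neuropeptide gene Gal (at least 54.8-fold, 0 against 115 UMIs), Tnfaip2 (at least 25.3-fold), Sprr1a (at least 18.6-fold), the chemokine genes Ccl2 (16.8-fold, 11.2 to 26.1) and Cxcl2 (22.4-fold), Hmga2, a chromatin protein of growing tissue (11.7-fold), Pvt1 (13.7-fold), Akap12 (9.69-fold, 8.47 to 11.1), the galectin gene Lgals3 (8.52-fold, 7.48 to 9.73), the matrix gene Tnc (12.5-fold) and Npvf (52.9-fold with 1 against 37 UMIs, 8.93 to 2146). Those named as higher were Ndst4 (at least 6.53-fold), AC149090.1 (5.14-fold), Slc26a7 (10.1-fold with 29 against 2 UMIs, 2.56 to 87.7), Shisal2b (3.51-fold), S100a3 (5.49-fold), the glutamate receptor gene Grin3a (4.11-fold), Col25a1 (6.64-fold), Etnppl (3.98-fold), the activity-regulated gene Arc (5.45-fold), Spc25 (2.25-fold), Rab4a (2.93-fold) and Wdfy1 (2.67-fold). Müller-like UMIs of the knockout-labelled OIR library came mainly from cluster 7 (77.2%).

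**Figure D2:**
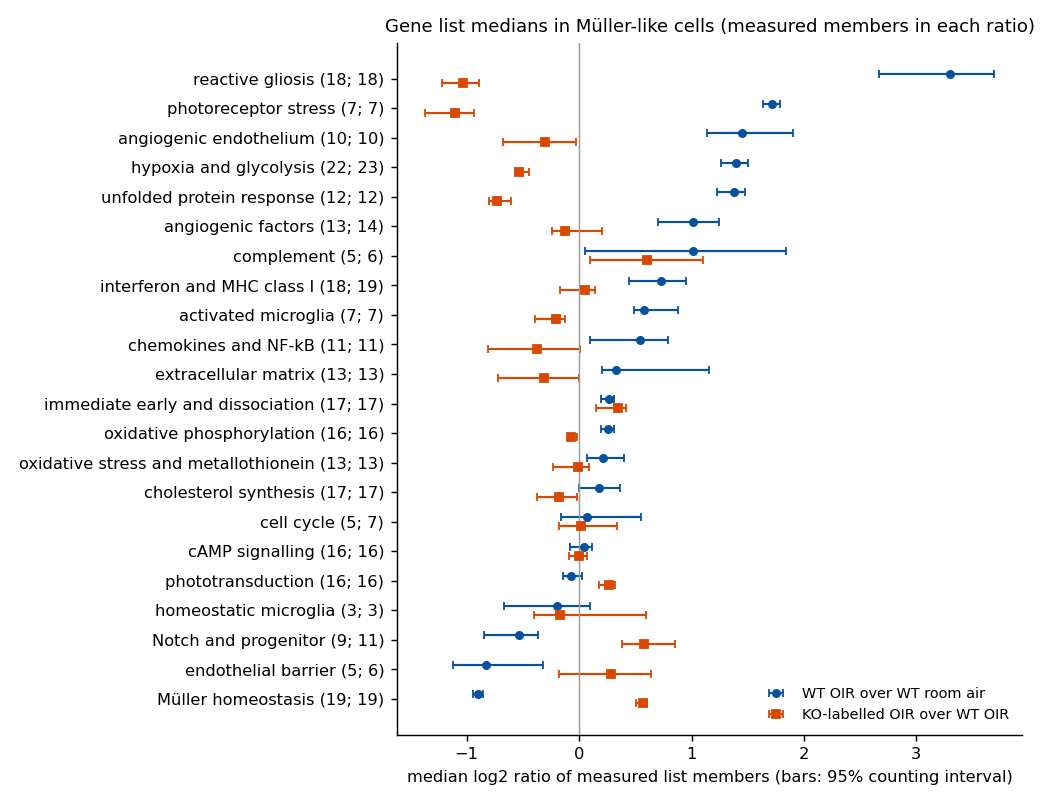
Median log2 ratio of the measured members of 22 gene lists in Müller-like cells for WT OIR over WT room air (circles) and knockout-labelled OIR over WT OIR (squares), with 95% counting intervals. Reactive gliosis lies at 3.30 and -1.03 and Müller homeostasis at -0.90 and 0.57, on opposite sides of 0. Both ratios use the WT OIR library, and a deviation of that library alone would also give opposite signs.

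**Figure D3:**
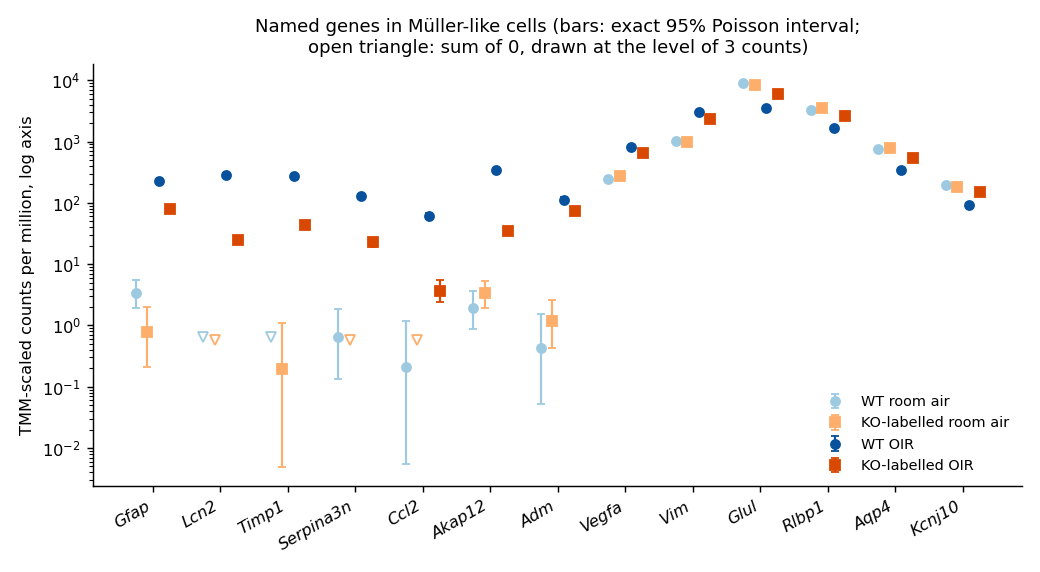
TMM-scaled CPM (log axis) of 13 named genes in Müller-like cells of the 4 libraries, with exact 95% Poisson intervals and with sums of 0 drawn as open triangles at the level of 3 counts. Gfap lies at 230.2 in WT OIR and 80.2 in knockout-labelled OIR, against 3.41 and 0.784 in room air.

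The effect of the genotype label in room air was taken from knockout-labelled RA over WT RA. The medians of the gliosis, homeostasis and hypoxia lists lay within 0.10 of 0, immediate early genes were higher in the knockout-labelled library, and a group of glucocorticoid-responsive genes was lower. The gliosis median was -0.10 (-0.21 to 0.02; 6 of 10 measured members lower), the homeostasis median 0.02 (-0.08 to 0.07) and the hypoxia median -0.06 (-0.12 to 0.02). Glul was 1.07-fold lower (1.05 to 1.08), Vim 1.07-fold lower (1.03 to 1.11), Vegfa 1.12-fold higher (1.04 to 1.22) and Rlbp1 1.11-fold higher (1.09 to 1.13), while the log2 ratios of Aqp4 (0.03, -0.04 to 0.09) and Kcnj10 (-0.10, -0.24 to 0.03) had intervals that held 0. Serpina3n had 3 and 0 UMIs, too few for a ratio. Gfap was 4.35-fold lower with 4 against 16 UMIs (1.40 to 17.9), and with 0 against 2 after thinning, too few for a ratio. Immediate early and dissociation genes were higher in the knockout-labelled library in 15 of 17, with a median of 0.44 (0.31 to 0.53; above all random lists). Photoreceptor stress genes were lower in 5 of 6 with a median of -0.50 (-0.67 to -0.32), oxidative stress and metallothionein genes had a median of -0.18 (-0.34 to -0.08), and the unfolded protein response list 0.25 (0.03 to 0.34). Phototransduction genes were lower in 13 of 16 with a median of -0.20 (-0.31 to -0.15), beside free RNA shares of 11.4% in this library and 14.7% in WT RA. The complement list had 3 measured members and a median of 0.88 (0.21 to 1.17). The complement median was -0.06 after thinning, -0.12 with no minimum of UMIs and -0.09 with at least 100 UMIs, and the phototransduction median was 0.03 in cells of at least 3000 UMIs. With Müller-like cells chosen by per-cell markers, Vegfa and Rlbp1 had log2 ratios of -0.016 and -0.035, and with the Optc cluster counted as Müller-like, Vim, Vegfa and Rlbp1 had 0.017, -0.006 and -0.04.

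By size, the genes lower in the knockout-labelled RA library were Fkbp5 (19.1-fold, 14.3 to 26.1), Arrdc2 (9.49-fold, 6.91 to 13.3), Etnppl (7.57-fold, 6.19 to 9.34), Ptk2b (14.2-fold, 5.76 to 45.0), Zbtb16 (6.195-fold, 4.97 to 7.80) and the sulfotransferase gene Sult1a1 (7.31-fold, 4.15 to 13.9). Fkbp5 and Zbtb16 are well-known targets of the glucocorticoid receptor. In CPM, Fkbp5 stood at 179.5 in WT RA against 9.40, 6.51 and 10.1 in the other libraries, and Etnppl at 162 against 21.4, 3.25 and 12.9, so that WT RA stood apart from the other 3. The genes named as higher were AC149090.1 (3.79-fold), the lipase gene Lipg (4.09-fold), Arsi (3.71-fold), the bicarbonate transporter gene Slc4a8 (2.82-fold), Fbxl7 (3.30-fold) and Dynlt1b (4.32-fold). Of these, Slc4a8, Dynlt1b and AC149090.1 also differed by genotype label in other classes.

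The response to OIR within the knockout-labelled libraries had the same direction as in WT for gliosis, homeostasis and hypoxia genes. In knockout-labelled OIR over knockout-labelled RA, all 16 measured gliosis genes were higher with a median of 1.56 (1.26 to 1.80; above all random lists), 16 of 19 homeostasis genes were lower with a median of -0.28 (-0.31 to -0.24), and 20 of 22 hypoxia genes were higher with a median of 0.90 (0.77 to 0.98). Gfap was 102-fold higher (39.7 to 377) and Timp1 218-fold (38.9 to 8657) from 1 UMI. Lcn2 was at least 42.3-fold, Serpina3n at least 38.7-fold and Areg at least 34.6-fold higher, Adm 61.5-fold (28.0 to 168), Vegfa 2.43-fold (2.29 to 2.59) and Vim 2.39-fold. Glul was 1.43-fold lower, Rlbp1 1.37-fold, Aqp4 1.45-fold and Kcnj10 1.23-fold, and the genes named as lower were the lens filament gene Bfsp2 (5.79-fold), Slco1c1 (4.47-fold), Crispld1 (3.82-fold), BC055402 (3.33-fold), Pebp4 (4.06-fold) and Papss2 (3.76-fold). Interferon and MHC class I genes had a median of 0.79 (0.56 to 0.92), complement genes 1.67 (1.08 to 2.29), phototransduction genes 0.47 (0.39 to 0.52) and the unfolded protein response list 0.24 (0.10 to 0.29).

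The difference of the 2 responses, knockout-labelled less WT on the log2 scale, was negative for gliosis genes and positive for homeostasis genes. The gliosis median was -0.87 (-1.29 to -0.48; 16 of 18 members negative), the hypoxia median -0.45 (-0.57 to -0.40), the unfolded protein response median -1.02 (-1.18 to -0.61) and the homeostasis median 0.60 (0.49 to 0.66). Among the genes with the most negative difference were Akap12 (-4.07), Mob3a (-4.66, -6.63 to -2.70), Lif, a cytokine that activates Stat3 in Müller glia (-4.73, -6.79 to -2.67), Egln3 (-4.34, -6.17 to -2.50) and Lgals3 (-2.97). Among the marker genes, Vegfa had a difference of -0.49 and Vim -0.27, and Glul had 0.82, Kcnj10 0.80, Aqp4 0.60 and Rlbp1 0.49. Gfap went the other way from its list, at 0.60 (-0.99 to 2.19), with 4 UMIs in knockout-labelled RA, and Serpina3n is given no difference, since its sum of 0 there makes the knockout-labelled response a bound. In the gliosis median, the 4 genes with a sum of 0 were set at 3 counts. Those with the most positive difference were Fkbp5 (4.89), Etnppl (4.91), Arrdc2 (3.98), Fam107a (4.77), Zbtb16 (3.62) and Sult1a1 (4.35), genes at their highest level in WT RA.

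Response genes were also chosen in a random part of the cells of both WT libraries and read in the remaining cells, so that counting noise in the choice did not favour WT. Differences between libraries are not removed by this. Genes peculiar to a WT library can still be chosen, and they would have a smaller ratio in the knockout-labelled libraries. Of the 756 Müller genes chosen as higher, the median log2 ratio was 1.36 in WT (1.31 to 1.39) and 0.64 in the knockout-labelled libraries (0.61 to 0.66), and 672 of them had the smaller ratio there. For the 570 genes chosen as lower, the medians were -1.15 (-1.17 to -1.10) and -0.36 (-0.37 to -0.32), with 549 nearer 0 in the knockout-labelled libraries. Rod-like cells behaved likewise for 222 higher genes (1.43 and 0.64) and 70 lower genes (-0.98 and -0.05). Bipolar-like cells did so for 157 higher genes (1.22 and 0.67) but not for 189 lower genes (-0.95 and -0.90), of which 98 had the smaller ratio in the knockout-labelled libraries. When Müller genes were chosen in the knockout-labelled libraries instead, the medians were 1.52 in WT and 1.12 in knockout-labelled for higher genes and -1.41 and -0.89 for lower ones. The values of this reverse choice in rod-like and bipolar-like cells are not reported here.

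**Figure D4:**
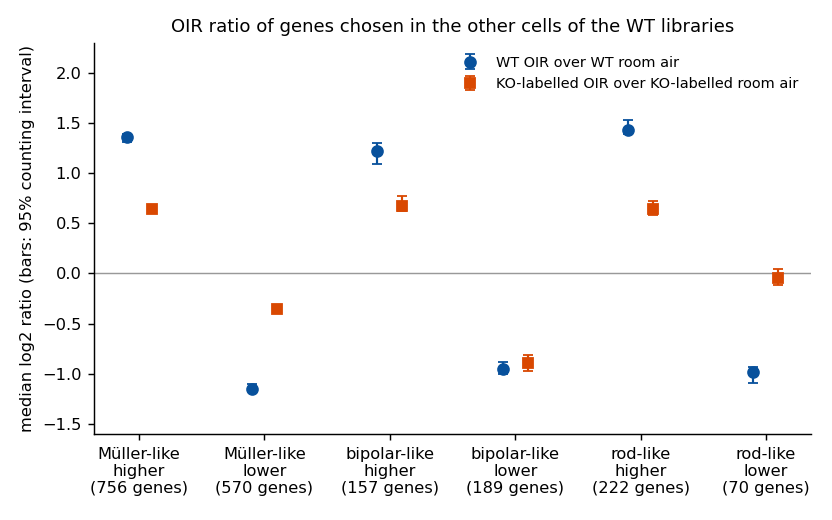
Median log2 OIR ratio, with 95% counting intervals, of genes chosen in 1 part of the WT cells and read in the remaining cells, in WT (circles) and knockout-labelled libraries (squares), for Müller-like, bipolar-like and rod-like cells. Müller-like medians are 1.36 and 0.64 for genes chosen as higher, while bipolar-like genes chosen as lower lie close together at -0.95 and -0.90.

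At the level of single cells, thinned to 1000 UMIs each, Gfap was detected in 0.131% of 762 Müller-like cells in WT RA and in 0 of 741 in knockout-labelled RA. At the limit of 3 counts set for a count of 0, the latter allows a share of up to 0.405%. The share was 11.3% of 797 cells in WT OIR (9.18 to 13.7) and 5.61% of 1123 in knockout-labelled OIR (4.34 to 7.12), beside 0.589% and 0.305% in rod-like cells, which should lack it. Serpina3n was detected in 7.91% (6.13 to 10.0) and 1.87% (1.16 to 2.84) of Müller-like cells in the OIR libraries, against 0.241% and 0.070% in rod-like cells. Vegfa was detected in 19.2%, 26.0%, 48.6% and 39.1% of Müller-like cells and 1.34%, 1.16%, 4.74% and 3.01% of rod-like cells, Ccl2 in 1.63% and 0.356% in the OIR libraries (rod-like cells 0.188% and 0.023%). Rapgef3 was detected in 0.656%, 0.810%, 1.004% and 0.623% (rod-like cells 0.028%, 0, 0.027% and 0.023%). Thinning left out 101, 97, 151 and 196 shallower Müller-like cells. Without it the shares in Müller-like cells were 0.695%, 0.358%, 27.8% and 13.9% for Gfap, 0.232%, 0, 19.4% and 5.16% for Serpina3n, 53.7%, 60.9%, 69.4% and 65.3% for Vegfa, 0.116%, 0, 2.32% and 0.455% for Ccl2 and 3.82%, 4.53%, 2.11% and 2.96% for Rapgef3, at median depths of 5748, 6150.5, 3327 and 4202 UMIs in Müller-like and 1150.0, 2146, 1227 and 1208 in rod-like cells. Reclustering of Müller-like cells alone gave 7 clusters, which are not compared between groups because the response genes define them.

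In endothelial-like cells, genes of sprouting vessels were higher in WT OIR than in WT RA and genes of the blood-retina barrier were lower, and both stood nearer the room-air level in the knockout-labelled OIR library. The angiogenic endothelium list was higher in 14 of 14 with a median of 2.38 (2.17 to 2.60), led by Esm1, a marker of tip cells (173-fold, 67.2 to 634), and Pgf (at least 91.0-fold), and it was lower in 14 of 14 in knockout-labelled OIR over WT OIR, with a median of -0.81 (-0.92 to -0.73). The barrier list had medians of -1.46 (-1.64 to -1.27; 9 of 10 lower) and 0.50 (0.33 to 0.60; 10 of 10 higher). Angiogenic factors had medians of 1.71 (1.21 to 2.04) and -1.49 (-1.88 to -1.30), and hypoxia genes 1.13 (0.91 to 1.29) and -0.72 (-0.83 to -0.63). Cell cycle genes did not follow: their median was 0.76 (0.44 to 1.16) in WT OIR over WT RA and 1.02 (0.88 to 1.196; 14 of 15 higher) in knockout-labelled OIR over WT OIR. Within the knockout-labelled libraries the cell cycle median was 3.44 (2.98 to 4.31), and in room air it was -0.94 (-1.49 to -0.49) for knockout-labelled over WT. By size, Acta2 (at least 94.4-fold) was higher and Zbtb16 (at least 70.4-fold), Sema3c (151-fold, to 3 UMIs, 51.2 to 739) and Paqr5 (71.7-fold) were lower in WT OIR. Zbtb16 stood at 102 CPM in WT RA and at 2.58 in knockout-labelled RA, so WT RA stood apart for it. In knockout-labelled OIR over WT OIR, Gkn3 (at least 37.0-fold) and the mitotic genes Ube2c (6.41-fold) and Cenpf (7.02-fold) were higher, and Acta2 (33.9-fold), Ankrd1 (at least 22.5-fold) and Thbs1 (12.9-fold) lower. Acta2 stands among the mural markers used to name the classes, and whether mural cells contributed it to this class was not tested.

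Mural-like cells were higher for hypoxia, chemokine, cell cycle and matrix genes in WT OIR than in WT RA, and lower for the same 4 lists in knockout-labelled OIR than in WT OIR. Hypoxia genes had medians of 2.05 (1.77 to 2.34; 20 of 22 higher) in WT OIR over WT RA and -0.81 (-0.95 to -0.66; 22 of 22 lower) in knockout-labelled OIR over WT OIR, chemokine and NF-kB genes 2.87 (1.85 to 3.54) and -1.39 (-1.71 to -1.18), cell cycle genes 2.19 (1.66 to 2.92) and -0.60 (-0.74 to -0.30), and extracellular matrix genes 1.46 (0.89 to 1.80) and -0.48 (-0.57 to -0.27). Ccl2 (at least 55.1-fold), Ube2c (at least 18.1-fold) and the collagen gene Col6a3 (29.0-fold) were higher in WT OIR, and Perp (70.6-fold) and the prostacyclin synthase gene Ptgis (at least 37.0-fold) lower. Ptgis stood at 96.4 CPM in WT RA against 2.85, 0 and 3.75 in the other libraries. Against WT OIR, the knockout-labelled library was lower for Mmp10 (at least 23.9-fold), Tnc (16.0-fold) and Mmp3 (at least 8.49-fold) and higher for Atp13a5 (8.35-fold), Pgm5 (5.47-fold) and Cep97 (7.49-fold, from 3 UMIs, 2.29 to 38.6). With 60, 51, 105 and 120 cells, this was the smallest class compared, and the median of all its genes was 0.11 in WT OIR over WT RA and, with CPM of the total, -0.13 in knockout-labelled OIR over knockout-labelled RA.

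Photoreceptors and bipolar cells carried a stress response in WT OIR that was smaller in the knockout-labelled OIR library. The photoreceptor stress list had a median of 4.39 (3.88 to 4.93; 8 of 8 higher) in rod-like cells, 2.11 (1.42 to 3.13; 5 of 5) in cone-like cells and 2.87 (2.26 to 3.46; 8 of 8) in bipolar-like cells for WT OIR over WT RA. For knockout-labelled OIR over WT OIR, the medians were -1.79 (-2.05 to -1.51; 9 of 9 lower), -1.59 (-2.19 to -1.13; 5 of 5) and -2.21 (-2.51 to -1.45; 8 of 8). In rod-like cells Edn2, the endothelin of injured photoreceptors, was at least 126-fold higher, Bcl3 at least 118-fold and Cebpd 103-fold (72.1 to 151) in WT OIR. Hypoxia genes had medians of 0.81 (0.64 to 0.88), 0.31 (0.16 to 0.48) and 0.87 (0.80 to 0.90) in rod-like, cone-like and bipolar-like cells, and -0.30 (-0.43 to -0.23), -0.13 (-0.31 to -0.10) and -0.66 (-0.71 to -0.48) against WT OIR. Rod-like phototransduction genes had medians of -0.39 (-0.40 to -0.36) and 0.22 (0.20 to 0.23), the gliosis list read in rod-like cells 2.98 (2.47 to 3.15) and -0.92 (-1.23 to -0.76), and bipolar-like immediate early genes 1.24 (0.99 to 1.70) and -0.62 (-0.86 to -0.32). Of that gliosis list, Gfap had 5.31 and Lcn2 8.08 CPM in rod-like cells of WT OIR, against 230.2 and 288 in Müller-like cells. Different clusters held the rod-like cells of each library, and cluster 0 held 25, 27, 2437 and 1051 of them, out of 5669, 3637, 5509 and 6374.

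Other genes named by size in rod-like cells were Selenbp1 (5.35-fold), Zim1 (13.4-fold, to 2 UMIs, 3.35 to 116) and the guanylate cyclase activator gene Guca1a (3.48-fold), lower in WT OIR. WT RA alone was high for Selenbp1, at 56.8 CPM against 11.2, 10.6 and 12.3. In knockout-labelled OIR over WT OIR, Slc22a29 (3.87-fold), Fndc1 (3.95-fold) and Slc22a30 (4.48-fold) were higher and Kctd8 (5.47-fold), Socs3 (5.95-fold) and Spidr (4.63-fold) lower. In cone-like cells Pcolce (at least 13.1-fold), Zbtb7c (49.6-fold, from 1 UMI, 8.49 to 1999.9) and Poteg (at least 9.99-fold) were higher and Lrp1b (16.0-fold), Tc2n (10.3-fold) and Selenbp1 (7.83-fold) lower in WT OIR. WT RA alone was high for these 3, at 121, 58.6 and 81.4 CPM against 3.39, 8.14 and 12.2 in knockout-labelled RA. The knockout-labelled OIR library was higher in cone-like cells for Wdfy1 (5.63-fold), AC149090.1 (3.44-fold) and Wscd2 (5.63-fold) and lower for Tnnc1 (at least 8.89-fold), Zbtb7c (17.1-fold, to 3 UMIs, 5.50 to 85.6) and Lrrc2 (9.50-fold). In bipolar-like cells the MHC class II gene H2-Ab1 (263-fold, from 1 UMI, 46.6 to 10458), A2m (102-fold) and Gipr (at least 39.3-fold) were higher and Cpne9 (18.5-fold, to 3 UMIs, 6.12 to 91.5), Col8a1 (8.87-fold) and Rprm (25.5-fold, to 1 UMI, 4.31 to 1032) lower in WT OIR. Against WT OIR, Cpne9 (11.8-fold, from 3 UMIs, 3.63 to 60.4), AC149090.1 (3.51-fold) and Plcxd3 (7.14-fold) were higher, and Nxph1 (81.2-fold, 31.5 to 299), Galntl6 (7.21-fold) and Kctd16 (4.96-fold) lower, in the knockout-labelled OIR library. The log2 ratio of Plcxd3 was -0.65 after thinning, with 2 against 4 UMIs. The bipolar-like clusters were also held in different proportions: cluster 19, led by genes that include Nxph1, had 55 of 660 bipolar-like cells in WT OIR and 18 of 496 in knockout-labelled OIR, and cluster 26 had 29 and 7.

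**Figure D5:**
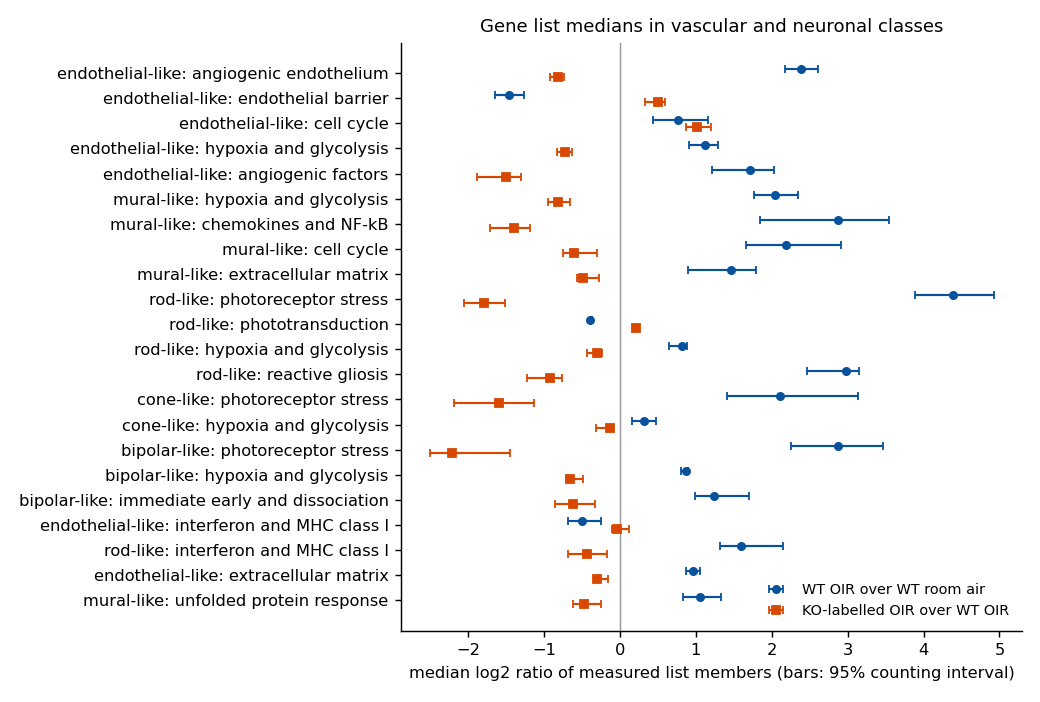
Median log2 ratio of the measured members of gene lists in endothelial-like, mural-like, rod-like, cone-like and bipolar-like cells for WT OIR over WT room air (circles) and knockout-labelled OIR over WT OIR (squares), with 95% counting intervals. Most pairs lie on opposite sides of 0, as photoreceptor stress in rod-like cells does at 4.39 and -1.79, and endothelial cell cycle genes lie above 0 in both, at 0.76 and 1.02. Both ratios use the WT OIR library, and a deviation of that library alone would also give opposite signs.

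A few genes differed by genotype label in room air and in OIR alike, in the sums of all cells and in at least 3 classes. Of 9 such genes, 8 had the same sign in both conditions. Wdfy1 was 2.33-fold higher in both conditions and Dynlt1b 3.87-fold and 2.76-fold in the knockout-labelled libraries. There, Gm49980 was 3.35-fold and 3.43-fold, AC149090.1 3.07-fold and 3.20-fold, and Slc4a8 1.92-fold and 2.40-fold higher. Gm17167 was 447-fold and 118-fold lower, with 823 and 300 UMIs in the WT libraries against 2 and 3 (log2 intervals -11.85 to -6.94 and -9.16 to -5.32), Gm15446 5.14-fold and 4.88-fold lower and the mitochondrial gene mt-Nd3 2.78-fold and 2.09-fold lower. Slc4a8 lies on chromosome 15 from 100761747 to 100823968, 3.04 Mb from Rapgef3, Wdfy1 on chromosome 1, Dynlt1b on chromosome 17, Gm49980 on chromosome 18, Gm17167 on chromosome 4, Gm15446 on chromosome 5 and AC149090.1 on an unplaced scaffold. Some of these, such as Dynlt1b and AC149090.1, belong to families of near-identical copies, among which the counting could divide reads. The haemoglobin gene Hbb-bs had opposite signs, 3.23-fold higher in room air and 2.91-fold lower in OIR in the knockout-labelled library.

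The labels give mixed sex for every library. Xist, the RNA that coats the inactive X chromosome in female cells, had 2, 5, 2 and 7 UMIs over all cells, while the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 10107, 8876, 8798 and 9492. Among cells of at least 5000 UMIs, a Y-linked UMI was present in 92.8% of 1482 cells in WT RA, 89.9% of 1758 in knockout-labelled RA, 89.4% of 1296 in WT OIR and 88.7% of 1573 in knockout-labelled OIR, and a Xist UMI in 1, 1, 0 and 2 of these cells. These values went against the label. Whether Xist was counted in full cannot be told from the matrices, but the share of cells with a Y-linked UMI does not depend on it.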

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

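No test of an explanation was run for the results in this part, and none of the differences in it was tested, since each group was 1 library. The median log2 ratios of 4 gene lists had opposite signs in the OIR response of the WT libraries and in that of the knockout-labelled libraries, with intervals on either side of 0. Phototransduction genes in cone-like cells had 0.18 in WT (0.07 to 0.25) and -0.15 in knockout-labelled libraries (-0.21 to -0.09), over 16 members each. Complement genes in mural-like cells had -0.34 (-0.57 to -0.10) and 0.415 (0.20 to 0.77), over 3 members each. Immediate early and dissociation genes in mural-like cells had 0.49 (0.31 to 0.69) and -0.27 (-0.44 to -0.17), over 17 members each. Homeostatic microglia genes read in rod-like cells, which should lack them, had -0.71 (-1.22 to -0.15) and 0.57 (0.00 to 0.84), over 3 members each.

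Several classes or clusters not used for gene ratios made up a larger share of cells in WT OIR than in WT RA. Microglia-like cells, the resident immune cells of the retina, were 1.85% in WT OIR (1.57 to 2.17) against 0.456% in WT RA, and 1.89% in knockout-labelled OIR (1.62 to 2.19) against 1.03% in knockout-labelled RA. Other immune-like cells were 0.485% in WT OIR (0.345 to 0.663), or 39 cells against 1 in WT RA, and numbered 7 and 10 in knockout-labelled RA and OIR. Red blood cell-like barcodes were 0.547% in WT OIR (0.398 to 0.734) against 0.160% in WT RA, while the knockout-labelled libraries had 0.112% in RA and 0.141% in OIR, with overlapping intervals. The cluster led by Optc held 0.784% of cells in WT OIR (0.603 to 1.001) against 0.111% in WT RA, while it held 0.962% in knockout-labelled RA and 0.943% in knockout-labelled OIR.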

How the results depend on the processing

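The alternatives chosen only after the data were seen were the Optc cluster counted as Müller-like and Müller-like cells of at least 3000 UMIs. With 1 library per group there was no threshold to pass and no replicate to leave out. No paired analysis was possible because each group had 1 library. Of 5455 values that 396 results took under the alternatives, 4695 stayed close to the value reported, within its counting interval or, for a count, within 1.5 times, 741 moved further, and 19 changed sign from a counting interval that did not hold 0, of which 7 were of single genes and 12 of list medians. Of the values that stayed close or moved, 82 also changed sign, each from an interval that held 0, among them Rapgef3 in knockout-labelled OIR over WT OIR, thinned (-0.48) and with equal weight per cell (-0.36), and the gliosis median of knockout-labelled RA over WT RA, thinned (0.037). The gliosis median of knockout-labelled OIR over WT OIR was negative under all 17 alternatives run for it, from -1.18 to -0.60, and the homeostasis median positive, from 0.42 to 0.58. Depth limits the genes with few UMIs and the classes with few cells: thinning to 1 depth, which discards UMIs, gave more of these 19 changes of sign than any other setting, and it left 12 ratios of single genes without a value, since both sums were at or under 3 counts or a sum of 0, set at 3 counts, passed the other sum. Except where a setting leaves out UMIs or cells by its construction, the cause was not tested for the values below.

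Values that changed sign from an interval that did not hold 0 in Müller-like cells were, for WT OIR over WT RA, endothelial barrier genes (0.004 with per-cell markers and 0.30 thinned) and complement genes (-0.068 with no minimum of UMIs). For knockout-labelled OIR over WT OIR they were oxidative phosphorylation genes (0.10 with equal weight per cell and 0.12 thinned) and complement genes (-0.052 with free RNA subtracted and -0.004 with at least 100 UMIs). In knockout-labelled RA over WT RA, Vegfa and Rlbp1 had -0.016 and -0.035 with per-cell markers. Vim, Vegfa and Rlbp1 had 0.017, -0.006 and -0.04 with the Optc cluster counted. In the same comparison, phototransduction genes had 0.03 in cells of at least 3000 UMIs, and complement genes -0.056 thinned, -0.12 with no minimum and -0.094 with at least 100 UMIs. Thinning also turned Plcxd3 in bipolar-like cells (-0.65, with 2 against 4 UMIs), and in endothelial-like cells extracellular matrix genes (0.001) and Mmp14 (0.007), all in knockout-labelled OIR over WT OIR.

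The share of Müller-like cells moved beyond its interval with at most 10% mitochondrial UMIs to 9.80% in WT RA, 10.6% in WT OIR and 13.1% in knockout-labelled OIR, and without a cell filter to 11.4% in WT RA and 15.2% in knockout-labelled OIR. Per-cell markers gave 8.99%, 9.59% and 12.5% in WT RA, WT OIR and knockout-labelled OIR, and counting the Optc cluster gave 14.4%, 12.6% and 15.2% in knockout-labelled RA, WT OIR and knockout-labelled OIR. Per-cell markers gave gliosis medians of 2.65 for WT OIR over WT RA and 1.21 for knockout-labelled OIR over knockout-labelled RA, where the Optc cluster counted gave 1.13. At least 100 UMIs gave 1.90 for WT OIR over WT RA. Thinned, the gliosis medians were 2.43 for WT OIR over WT RA, -0.60 for knockout-labelled OIR over WT OIR and 0.037 for knockout-labelled RA over WT RA. Thinned Rapgef3 was -0.48 for knockout-labelled OIR over WT OIR, with 8 against 8 UMIs.

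In Müller-like cells the split comparison kept the smaller median in the knockout-labelled libraries under every alternative run. Genes chosen as higher, read in WT, moved to 1.39 with at least 500 genes, 1.48 with at most 10% mitochondrial UMIs, 1.47 without a cell filter, 1.39 without doublet removal, and 1.43 at resolution 0.6. They moved to 1.51 with per-cell markers, 1.61 with the Optc cluster, 1.40 with at least 3000 UMIs, 1.57 thinned, 1.28 with equal weight per cell, and 1.40 with free RNA subtracted. The other values were 1.52 when chosen in the knockout-labelled libraries, 2.002 with a 2-fold bound and 1.54 with the parts exchanged. Read in the knockout-labelled libraries, they moved to 0.71 with at most 10% mitochondrial UMIs, 0.67 at resolution 0.6, 0.44 with per-cell markers, 0.46 with the Optc cluster, 0.58 with CPM of the total, 0.84 thinned, 0.50 with equal weight per cell, 1.12 when chosen there, 0.91 with a 2-fold bound and 0.68 with the parts exchanged. Genes chosen as lower, read in WT, moved to -1.24 with at least 500 genes, -1.26 with at most 10% mitochondrial UMIs, -1.18 without doublet removal, and -1.21 at resolution 1.5. They moved to -1.10 with per-cell markers, -1.29 with at least 3000 UMIs, -1.24 thinned and -0.95 with equal weight per cell. The other values were -1.41 when chosen in the knockout-labelled libraries, -1.59 with a 2-fold bound and -1.23 with the parts exchanged. Read in the knockout-labelled libraries, they moved to -0.38 with at most 10% mitochondrial UMIs or without doublet removal, -0.39 with Scrublet's automatic threshold, -0.30 with per-cell markers or with free RNA subtracted, -0.31 with the Optc cluster, -0.42 with CPM of the total, -0.37 with median-of-ratios scaling, -0.89 when chosen there and -0.49 with a 2-fold bound.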

Other observations

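Tests chosen only after the result was seen were those of a milder change across the whole retina, of the 6 genes read in OIR and of genes near Rapgef3, as were the wider set of shared genes and the reading of the depth and clock intervals by the range each cause needed. Classes other than Müller glia differed in gene groups not yet described. In endothelial-like cells, interferon and MHC class I genes were lower in WT OIR than in WT RA in 15 of 20, with a median log2 ratio of -0.49 (-0.69 to -0.25), among them Irf7, the interferon-induced regulator (3.56-fold lower, 2.42 to 5.30), and Ifit3 (7.47-fold, 3.67 to 16.8). Rod-like cells went the other way, with 8 of 8 higher and a median of 1.60 (1.33 to 2.15), for example the class I gene H2-D1 (6.26-fold, 4.65 to 8.58). In knockout-labelled OIR over WT OIR these medians were -0.03 (-0.11 to 0.12) and -0.43 (-0.69 to -0.16), and H2-D1 was 2.52-fold lower in rod-like cells (2.08 to 3.08).

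Extracellular matrix genes in endothelial-like cells were higher in WT OIR than in WT RA in 7 of 9, with a median of 0.97 (0.87 to 1.06), led by the membrane metalloproteinase gene Mmp14 (7.05-fold, 4.61 to 11.3), whereas the protease inhibitor gene Timp3 was 4.19-fold lower (3.47 to 5.07). In knockout-labelled OIR over WT OIR, 9 of 12 were lower, with a median of -0.30 (-0.34 to -0.16), and Mmp14 was 1.49-fold lower (1.27 to 1.74), but after thinning the log2 values of the list and of Mmp14 were 0.001 and 0.007. Unfolded protein response genes in mural-like cells had medians of 1.06 (0.84 to 1.33; 7 of 9 higher) and -0.47 (-0.61 to -0.24; 8 of 10 lower) in the same comparisons. There Hspa5, the chaperone BiP of the endoplasmic reticulum, was 3.29-fold higher (2.72 to 4.01) and then 1.72-fold lower (1.57 to 1.89), and the transcription factor gene Xbp1 3.87-fold higher (2.41 to 6.55) and then 1.97-fold lower (1.56 to 2.49).

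The first pattern weighed was the lower gliosis median of knockout-labelled OIR over WT OIR in Müller-like cells, -1.03. Free RNA from other cells as the whole cause needed a median within 0.25 of 0 once the pooled profile was subtracted, and the median was -1.18 (-1.42 to -0.93). A difference in depth per cell as the whole cause needed the same after thinning, and the median was -0.60 (-0.96 to -0.40), outside that range. Its interval also crossed the bound of -0.5 set beforehand for excluding depth, so depth may account for part of the gap. The thinned median is taken over members that keep at least 20 UMIs, however, and may rest on fewer genes. Without thinning, the median was -0.98 with equal weight per cell and -1.10 in cells of at least 3000 UMIs. A milder change across the whole knockout-labelled OIR retina stayed open: photoreceptor stress genes in rod-like cells had a median of -1.79 (-2.06 to -1.51), but the list shares Fgf2, Stat3 and Socs3 with the gliosis list, and neither the lower genes of bipolar-like cells nor endothelial cell cycle genes followed. An effect of Epac1 in Müller glia, an effect elsewhere in the retina and a weaker OIR in the animals of that library all stayed open, since each group was 1 library. So did any other difference between the WT and knockout-labelled animals, which cannot be told apart from the genotype label.

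The next pattern was the high level of Fkbp5, Etnppl, Arrdc2, Zbtb16, Ptk2b and Sult1a1 in Müller-like cells of WT RA. A lower level in the knockout-labelled libraries whatever the oxygen condition needed these 6 genes to be lower in knockout-labelled OIR than in WT OIR as well. Their median there was 0.865 (0.56 to 1.35). Most of these genes were already far lower in WT OIR than in WT RA, so a further drop could hardly show. This test therefore cannot exclude an effect of the genotype label, including one confined to room air. A different time of day at harvest needed a difference of 1 or more between clock genes of opposite phase in all cells, and the difference was 0.24 (0.12 to 0.33), although its upper end passed the bound of 0.3 set beforehand. Stronger glucocorticoid signalling in the animals of the WT RA library stayed open as a hypothesis: further targets of the glucocorticoid receptor, such as Tsc22d3 and Klf9, were lower in knockout-labelled RA than in WT RA in 7 of 7 measured, with a median of -1.08 (-1.34 to -0.97). The medians of the measured members of that list were -1.74 in WT OIR over WT RA (7 genes, of which Sgk1 alone was higher), -0.17 in knockout-labelled OIR over knockout-labelled RA (6 genes) and 0.54 in knockout-labelled OIR over WT OIR (0.38 to 0.65; 5 of 6 higher), so WT OIR differed as well, and part of the difference between the 2 OIR responses may lie in the WT RA library.

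The last pattern was the set of 9 genes that differed by genotype label in several classes in both conditions. An exchange of labels between 1 WT and 1 knockout-labelled library would make opposite signs outnumber equal ones, and there were 8.0 genes of the same sign for each gene of opposite sign, although an exchange of both pairs would leave no trace in this count. In the sums of all cells with no minimum of classes, 53 genes had the same sign and 37 the opposite one. This excess of equal signs was smaller than the ratio set beforehand for arguing against an exchange. DNA of another strain beside Rapgef3 cannot be told from other causes, since only 1 gene of the set, Slc4a8, lay within 10 Mb of it against 0.088 by its share of the genome's measured genes, and 1 gene is too few to decide. In the wider set 3 genes lay there, Zfp641, Fkbp11 and Slc4a8, against 0.583. These numbers reach the bounds set for this cause, but the bounds and the wider set were chosen after the result was seen, so the cause stayed open. The same-sign genes of the first set other than Slc4a8 lie on other chromosomes, an unplaced scaffold or the mitochondrial genome. Whether the WT and knockout-labelled animals differed in DNA away from Rapgef3 was not tested.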
